A study of Mus musculus and Homo sapiens with 82 samples.

How the data were processed

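The analysis used the deposited tables of raw counts, 1 for each macrophage set and 1 for the colon biopsies, with 1 column per library and 1 gene per line. The values were whole numbers in every library, and 0 columns of per-library values were left unused. Per the submitters' notes, total RNA was made into stranded TruSeq mRNA libraries, sequenced as 35 bp read pairs on a NextSeq 500, trimmed with Trim Galore 0.6.4 and aligned with STAR 2.7.3a, and gene counts were made with featureCounts of Subread 1.6.3; the notes also name limma 3.50.3 and the builds mm10, GRCh38 and hg38. The gene annotation used for counting is not given in the sources used here. Counts of 1 to 20 were even in 70% of cases in the first set, 71% in the second and 60.5% in colon, so both mates of a pair appear to be counted at least in part.

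Of the 55401 mouse gene identifiers 54349 matched the GENCODE vM21 table for GRCm38/mm10, or 55141 with the version number left aside, and gene positions were taken from it; human positions were not used. Before any step 66 genes linked to sex were removed from the colon counts. Columns were matched to samples by the names in the labels. The replicate numbers of the untreated Nod2-deficient libraries of the first set could not be matched to columns, so their 2 columns are known by group alone. No 2 libraries were identical, and the noise between replicates was 3.6 to 10.9 times that of counting in the first set, 3.34 to 18 times in the second and 13.8 to 149 times in colon. Residuals of libraries sharing a replicate number correlated between groups at r = −0.12 to 0.41 over 8 pairs of groups in the first set (median 0.04, 2 above 0.1) and −0.42 to 0.19 over 45 pairs of libraries in the second (median −0.02). The numbers were not used as pairs, and a replicate block was tried beside.

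Each dataset was fitted as a whole with edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr, TMM scaling, 1 mean per group, robust quasi-likelihood F tests, and Benjamini-Hochberg adjustment over all genes tested with a threshold of 0.05. This left 17224 genes in the first set, 16228 in the second and 22620 in colon, with common biological coefficients of variation of 0.0552, 0.0964 and 0.417. A difference between 2 responses was tested as an interaction in the same fit. Fold changes are log2 and SEs come from the F statistic; a gene "rose", "fell" or "was called" only if it passed the threshold. CPM values use total counts with no pseudocount. In simulated counts with known changes edgeR recovered 62.1, 75.8 and 53% of genes changed by 1 log2 unit in the 2 sets and colon. False calls were 5, 4 and 7 of 16714, 15907 and 22024 genes. The 0 of 20 unchanged lists called in each do not test real, correlated lists.

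Gene lists (27 for mouse and 30 for human) were written before the data were examined, as were the comparisons, the tests, the other settings to be tried and the rule for naming genes. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, adjusted over the lists of a comparison; the adjusted p of camera with an estimated correlation is given beside each, and only 59 of the 378 calls made over all comparisons hold with it. None of the calls in colon does. fry was run beside camera. A list's count "adjusted over the list" is given where it differs from the count over all genes tested. The rule named in every comparison Pglyrp1, Nod2 and Arhgef2; among genes past the threshold with a mean log2 CPM of at least 1 and, in macrophages, no overlap between the libraries of the 2 groups, the 10 largest rises and 10 largest falls, leaving out clone-like names and antigen receptor segments; and up to 4 members of each list with the smallest adjusted p. Of these the text names a part, and a gene so named may be given in other comparisons.

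Alternatives were RLE size factors, no low-count filter, limma-voom (with sample quality weights in colon), DESeq2 1.42.0 and, in macrophages only, a replicate block and leaving out 1 library at a time. With 1 library left in a group, edgeR takes its spread from the other groups. The shared response to both compounds was compared with 20 simulations of unchanged groups against shared controls, drawn with the fitted dispersions. Genes called in wild type of the first set were followed in the second set by their median fold change and fry. Correlations in colon were tested by permutation with SciPy 1.17.1 in Python 3.11.15. These tests used 100000 resamples, or were exact in sets of 4, 6 or 8 biopsies. The share of mitochondrially encoded transcripts was tested by permutation in R with 100000 resamples. Figures were drawn with matplotlib 3.10.9.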

Results

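Gene expression was measured by RNA sequencing in mouse bone marrow-derived macrophages, grown from marrow with the growth factor M-CSF, and in human colon biopsies. The macrophages came in 2 sets. The first set held 18 libraries in 9 groups of 2: wild-type (C57BL6), Pglyrp1-deficient and Nod2-deficient cells, each left untreated, treated with MDP (muramyl dipeptide, the peptidoglycan fragment sensed by NOD2) or treated with GMTP. The structure of GMTP is not given in the sources used here. The second set held 36 libraries in 12 groups of 3 and added cells deficient in Arhgef2, which encodes GEF-H1, a microtubule-bound activator of RhoA. Doses and treatment times were not given in the labels. The 28 colon biopsies were labelled healthy (10), inactive ulcerative colitis (6) and active ulcerative colitis (12). Total counts per library ranged from 105.6 to 143.5 M in the first macrophage set, from 41.9 to 62.8 M in the second and from 30.9 to 45.7 M in the biopsies. A gene with no count in a library was therefore below 0.0209 to 0.0284 counts per 1 M counts (CPM) in the first set, 0.0478 to 0.0716 in the second and 0.0657 to 0.0971 in colon, taking 3 counts as the limit. These limits cover counting error only and are up to 2-fold higher if both mates of a pair were counted. Log2 fold changes are given ± SE from the edgeR fit and CPM as mean ± SD. Nothing states that replicate libraries came from separate cultures or animals, so the p-values in macrophages measure only the spread between these libraries.

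The 3 targeted genes were examined first in every macrophage library. In the first set Nod2 (ENSMUSG00000055994.15, chromosome 8: 88647315–88688474 in GRCm38/mm10) stood at 10.6 ± 3.2 CPM in the 6 wild-type libraries, at 9.91 ± 2.02 CPM in the 6 Pglyrp1-deficient libraries and at 1.88 ± 0.163 CPM in the 6 Nod2-deficient libraries. Pglyrp1 (ENSMUSG00000030413.7, chromosome 7: 18871331–18890459) was close to the detection limit in this set, with 1 to 13 counts per wild-type library and 0 to 5 counts per Pglyrp1-deficient library. That is too few for a fold change. Arhgef2 (ENSMUSG00000028059.16, chromosome 3: 88605966–88648052), which was not targeted here, stood at 243 ± 16.7 CPM in wild type, 260 ± 7.87 CPM in Pglyrp1-deficient and 202 ± 2.64 CPM in Nod2-deficient libraries.

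In the second set the targeted genes went against the label in 6 of the 36 libraries. Among the other 30, Arhgef2 stood at 280 ± 5.22 CPM in wild type and 28.1 ± 2.53 CPM in Arhgef2-deficient libraries. Nod2 stood at 8.33 ± 0.935 CPM in wild type and 2.81 ± 0.438 CPM in Nod2-deficient libraries. Pglyrp1 stood at 0.654 ± 0.116 CPM in wild type and 0.0226 ± 0.0304 CPM (0 to 4 counts) in Pglyrp1-deficient libraries. The libraries labelled untreated Nod2 knockout, replicates 1 and 2, held Nod2 at 7.82 and 7.93 CPM and Pglyrp1 at no more than 0.0319 CPM. Those labelled untreated Pglyrp1 knockout, replicates 1 and 2, held Arhgef2 at 32.6 and 31.7 CPM and Pglyrp1 at 0.618 and 0.645 CPM. Those labelled Arhgef2 knockout with MDP, replicates 2 and 3, held Arhgef2 at 245 and 249 CPM and Nod2 at 2.39 and 2.69 CPM. No library was relabelled. Comparisons that use these 6 libraries are given under the labels and in brief, and the knockouts of Pglyrp1 and Nod2 are described from the first set.

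**Figure D1:**
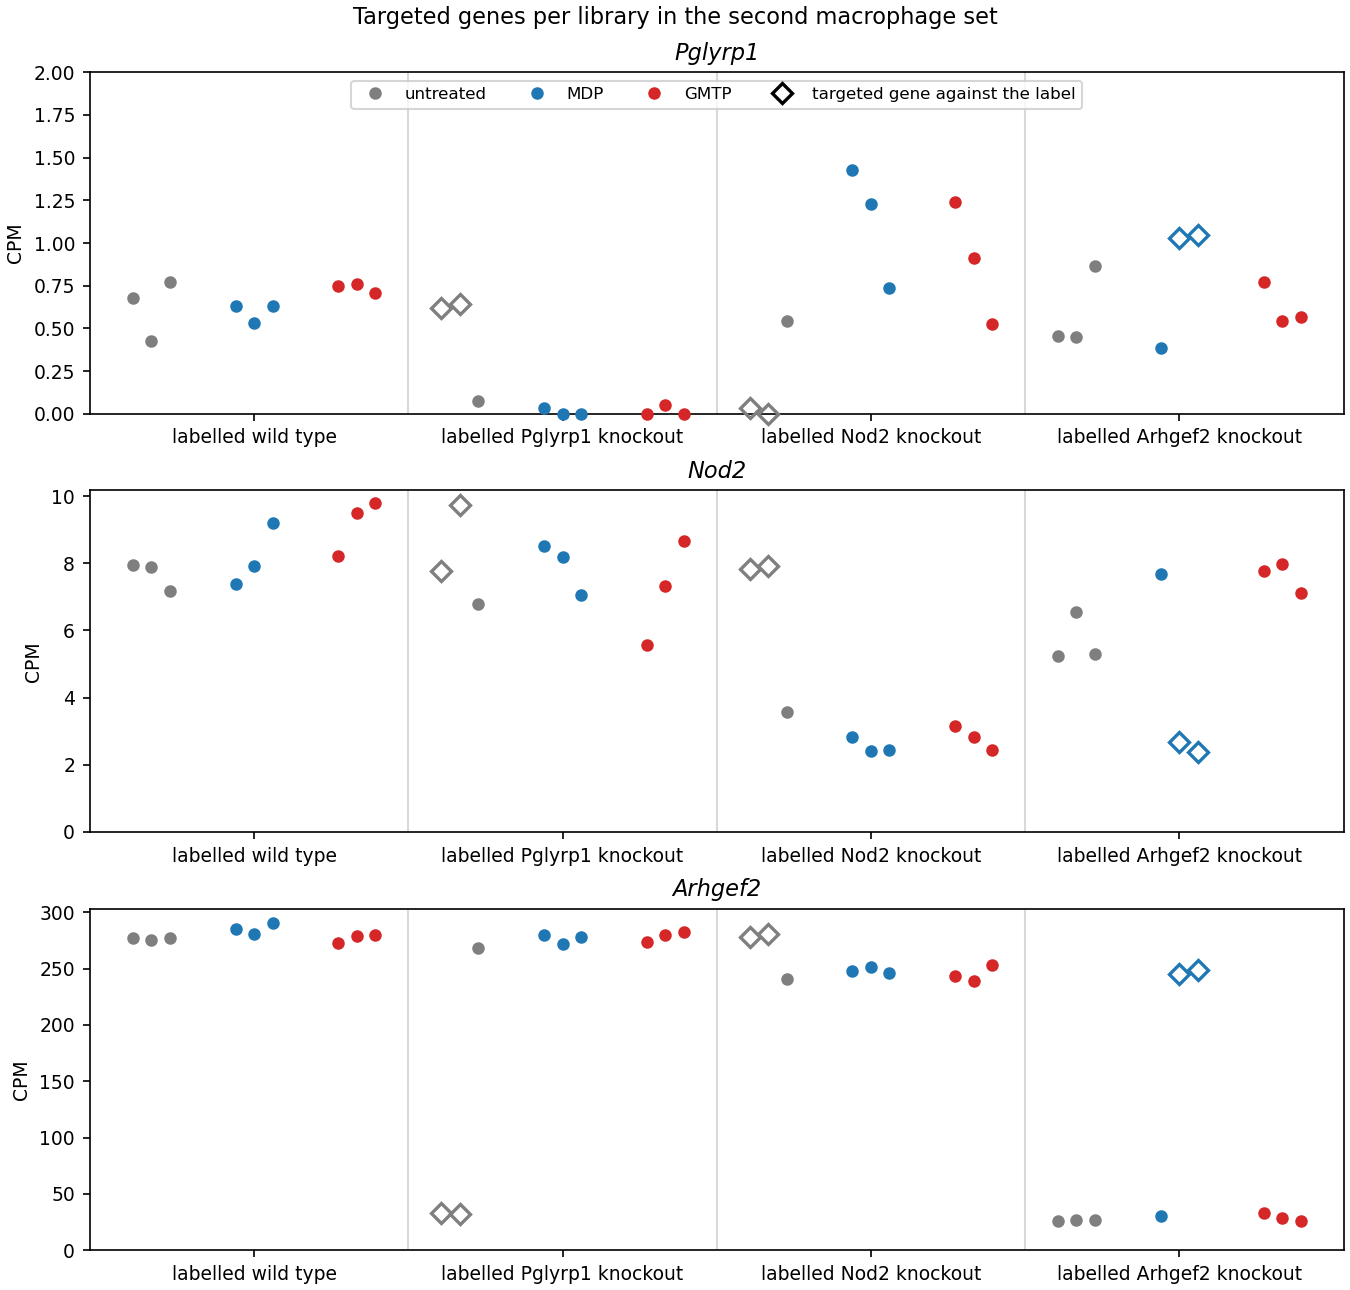
CPM (linear axis) of Pglyrp1, Nod2 and Arhgef2 in each of the 36 libraries of the second macrophage set, 3 per group, by labelled genotype and treatment. Open diamonds mark the 6 libraries in which a targeted gene went against the label, such as Arhgef2 at 245 and 249 CPM in 2 libraries labelled Arhgef2 knockout.

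Wild-type macrophages of the first set were compared with and without MDP, a NOD2 ligand. Slfn1 rose by 4.25 ± 0.10 and Ifit1bl1 by 4.15 ± 0.09. Irf7, a transcription factor that amplifies type I interferon, rose by 2.78 ± 0.05 and Mx1, an antiviral GTPase, by 2.7 ± 0.06 (n = 2 per group, edgeR adjusted p at most 2.1e-15). All 28 measured type I interferon-stimulated genes rose, with a median log2 fold change of 2.01 (camera adjusted p = 4.5e-51, adjusted p = 0.0179 with estimated correlation). Of 15 guanylate-binding proteins and interferon gamma targets 13 rose, among them Gbp2 (3.24 ± 0.06) and Iigp1 (3.26 ± 0.09), which attack vacuoles holding microbes (median 1.80, adjusted p = 3.01e-20, adjusted p = 0.0179 with estimated correlation). Antigen presentation followed, with 15 of 16 genes higher, including the peptide transporter Tap1 (1.53 ± 0.05) and the costimulator Cd86 (1.89 ± 0.08). The median was 0.87 (adjusted p = 3.01e-20, adjusted p = 0.0263 with estimated correlation).

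MDP also raised 13 of 23 inflammatory cytokines and chemokines in wild type, or 14 adjusted over the list, with 1 lower by that count. Il1b rose by 2.52 ± 0.24 (edgeR adjusted p = 3.32e-07), Ccl5 by 2.23 ± 0.06 and Acod1, the itaconate-producing enzyme, by 3.56 ± 0.22. The cytokine list had a median of 0.65 (camera adjusted p = 4.57e-05, adjusted p = 0.362 with estimated correlation). Of 22 NF-kB target and feedback genes 16 rose, such as Sod2 (1.39 ± 0.06), and 4 fell, such as Cd83 (−0.79 ± 0.06; median 0.35, adjusted p = 3.92e-06, adjusted p = 0.202 with estimated correlation). Of 16 inflammasome and pyroptosis genes 10 rose, or 12 adjusted over the list, with Casp4 at 0.99 ± 0.06, and 3 fell (median 0.36, adjusted p = 0.000119, adjusted p = 0.0179 with estimated correlation). Proliferation genes moved the other way. Of these, 24 of 25 cell cycle genes fell, including Ccna2 (−1.65 ± 0.09) and Rrm2 (−1.38 ± 0.08). Their median was −0.83 (adjusted p = 3.07e-22, adjusted p = 0.0179 with estimated correlation). The immediate early genes Myc (−1.95 ± 0.10) and Egr2 (−1.05 ± 0.06) fell. Nes, an intermediate filament gene, fell by 2.66 ± 0.08. The receptor genes Nod1 (1.03 ± 0.06) and Nod2 (0.98 ± 0.09, edgeR adjusted p = 5.32e-09) rose, while Arhgef2 was not called (0.09 ± 0.04, adjusted p = 0.0873). In total 2845 of 17224 genes rose and 2408 fell, of which 534 and 454 changed at least 2-fold.

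GMTP was compared with no treatment in the same cells. Large rises included inflammatory genes. Il1b rose by 5.59 ± 0.23, Socs3, a feedback inhibitor of cytokine receptors, by 4.71 ± 0.23 and Acod1 by 3.75 ± 0.22. Also higher were the orphan receptor gene Gpr84 by 3.47 ± 0.23, the acute-phase gene Saa3 by 3.35 ± 0.07 and the C-type lectin receptor gene Clec4e by 3.15 ± 0.23 (n = 2 per group, edgeR adjusted p at most 2.61e-06). Of 23 cytokines and chemokines 17 rose, with the neutrophil attractant Cxcl2 at 2.50 ± 0.23 (median 1.15, camera adjusted p = 1.93e-11, adjusted p = 0.0836 with estimated correlation). Of 22 NF-kB genes 18 rose, such as Sod2 (1.88 ± 0.06) and Bcl3 (2.11 ± 0.09; median 0.74, adjusted p = 3.27e-19, adjusted p = 0.0204 with estimated correlation). All 28 type I interferon-stimulated genes rose with GMTP as well, Mx1 by 2.09 ± 0.06 and Irf7 by 1.57 ± 0.05. The list had a median of 1.55 (adjusted p = 1.34e-52, adjusted p = 0.0204 with estimated correlation). Guanylate-binding proteins and interferon gamma targets had 12 genes higher and 1 lower, with Gbp7 at 2.73 ± 0.07 (median 1.32, adjusted p = 1.02e-15, adjusted p = 0.0204 with estimated correlation).

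Beyond inflammation, GMTP raised 18 of 20 cholesterol synthesis genes, such as Mvd (0.73 ± 0.08). Their median was 0.41 (camera adjusted p = 1.34e-13, adjusted p = 0.0169 with estimated correlation). Peptidoglycan sensing genes had 11 of 17 higher and 1 lower, with Tlr2 at 1.66 ± 0.06, Nlrp3 at 1.03 ± 0.07 and Nod2 at 1.03 ± 0.09 (median 0.25, adjusted p = 3.51e-05, adjusted p = 0.0578 with estimated correlation). Arhgef2 rose slightly (0.20 ± 0.04, edgeR adjusted p = 0.000577). Cell cycle genes fell less than with MDP. Of 25, 20 were lower, or 22 adjusted over the list, with a median of −0.41 (adjusted p = 1.27e-11, adjusted p = 0.0561 with estimated correlation). Macrophage identity genes had 13 of 17 higher and 2 lower, or 14 higher adjusted over the list (median 0.27, adjusted p = 3.32e-08, adjusted p = 0.036 with estimated correlation). The largest falls included the phosphodiesterase gene Pde1c (−2.12 ± 0.23) and the GABA receptor gene Gabbr2 (−1.98 ± 0.10). GMTP raised 2250 genes and lowered 1994, with 357 and 286 changing at least 2-fold.

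The compounds were then compared in wild-type cells of the first set. GMTP gave higher levels of Il12b, an interleukin-12 subunit gene (4.94 ± 0.71), Socs3 (3.86 ± 0.21), Il1b (3.07 ± 0.19), Cxcl2 (1.91 ± 0.22), Nlrp3 (1.25 ± 0.07) and the LPS co-receptor gene Cd14 (1.02 ± 0.06) than MDP did (n = 2 per group, edgeR adjusted p at most 0.000708). MDP gave higher levels of the interferon-induced surface antigen gene Ly6a (−2.77 ± 0.07 for GMTP minus MDP), the T cell attractants Cxcl9 (−1.94 ± 0.09) and Ccl5 (−1.64 ± 0.06), Irf7 (−1.21 ± 0.05) and Ciita, the regulator of MHC class II (−1.03 ± 0.05). By list, 27 of 28 interferon-stimulated genes were lower and 1 higher with GMTP (median −0.53, camera adjusted p = 2.17e-28, adjusted p = 0.0623 with estimated correlation). Antigen presentation genes were lower in 15 of 16 cases, or 16 adjusted over the list (median −0.57, adjusted p = 1.28e-21, adjusted p = 0.0504 with estimated correlation). NF-kB genes went the other way, with 14 of 22 higher with GMTP (median 0.46, adjusted p = 1.41e-13, adjusted p = 0.0623 with estimated correlation). So did cell cycle genes, with 21 of 25 higher, or 22 adjusted over the list, and Ccna2 at 1.14 ± 0.09 (median 0.49, adjusted p = 5.09e-17, adjusted p = 0.0504 with estimated correlation). Cholesterol synthesis genes were higher in 14 of 20 cases, Sqle by 0.66 ± 0.06 (adjusted p = 1.41e-13, adjusted p = 0.0175 with estimated correlation). Nod2 itself was not called between the compounds (0.05 ± 0.09, adjusted p = 0.769). In all, 1576 genes were higher and 1846 lower with GMTP.

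MDP and GMTP raised 1594 genes in common and lowered 1243 in common in the first set, where 372 and 279 were expected by chance. The 2 responses correlated across genes with r = 0.61 and a covariance of 0.342. Both were measured against the same 2 untreated libraries. Unchanged groups simulated against shared controls gave r = 0.51 and a covariance of 0.114, with 0.3 genes called higher and 0.2 lower in both. Part of the excess over the expected overlap may therefore come from the shared controls. Genes are not independent replicates.

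Nod2-deficient macrophages were treated alike to ask which part of each response needs the receptor. MDP moved none of the genes that led the wild-type response. Irf7 changed by −0.03, Gbp2 by −0.01 and Mx1 by 0.04, and Ccl5, the cytokine gene nearest to the threshold, by −0.29 ± 0.06 (n = 2 per group, edgeR adjusted p at least 0.253). Ccl5 was called without MDP replicate 1 (−0.22) or replicate 2 (−0.37). With edgeR 0 genes were called, while 1002 had an unadjusted p under 0.05, DESeq2 called 11 and limma-voom 0. Without Nod2 knockout MDP replicate 1 the count was 791, without replicate 2 it was 3, and without either untreated library it was 1. By list, lysosome and autophagy genes (median 0.04, camera adjusted p = 0.0182) and glycolysis and hypoxia genes (median 0.03, adjusted p = 0.039) were higher and cell cycle genes lower (median −0.09, adjusted p = 0.0283), each at adjusted p = 0.585 with estimated correlation. Of their genes 0 were called, or 1 cell cycle gene adjusted over the list. The wild-type and knockout responses to MDP differed for 3263 genes, 1497 higher and 1766 lower in the knockout. All 28 type I interferon-stimulated genes responded less, by a median of −2.13 (camera adjusted p = 3.58e-65, adjusted p = 0.0128 with estimated correlation). Ifit1bl1 differed by −4.41 ± 0.12 and Irf7 by −2.81 ± 0.07. Of 15 guanylate-binding proteins and interferon gamma targets 13 responded less, Gbp2 by −3.25 ± 0.08 (median −2.57, adjusted p = 7.59e-24, adjusted p = 0.0128 with estimated correlation). The same held for 11 of 23 cytokines and chemokines, or 12 adjusted over the list, with Nos2, the inducible nitric oxide synthase gene, at −5.09 ± 0.55 and Ccl5 at −2.52 ± 0.08 (median −0.71, adjusted p = 0.000123, adjusted p = 0.395 with estimated correlation). It also held for 15 of 16 antigen presentation genes, such as Tap1 (−1.52 ± 0.07; adjusted p = 6.32e-23, adjusted p = 0.0174 with estimated correlation). Genes that MDP lowered in wild type differed in the other direction, with Nes at 2.67 ± 0.11, Ccna2 at 1.51 ± 0.13 and 22 of 25 cell cycle genes higher (median 0.75, adjusted p = 5.15e-21, adjusted p = 0.0174 with estimated correlation).

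GMTP changed 49 genes in Nod2-deficient cells of the first set, 38 upward and 11 downward. The rises were small, as for the transcription factor genes Foxn3 (0.45 ± 0.07) and Rest (0.43 ± 0.06) and the surface signal gene Cd47 (0.34 ± 0.04). The falls included the noncoding RNA genes Neat1 (−0.62 ± 0.09) and Firre (−0.58 ± 0.09) and Myc (−0.50 ± 0.11; n = 2 per group, edgeR adjusted p at most 0.0489). The count was 9 without GMTP replicate 1, 6 without GMTP replicate 2, and 11 or 7 without one or the other untreated library. Myc was called in none of these 4 fits (−0.49 to −0.51). Among 28 interferon-stimulated genes 0 were called, or 2 higher adjusted over the list (median 0.07, camera adjusted p = 0.00131, adjusted p = 0.915 with estimated correlation). The response to GMTP differed from wild type for 2974 genes, 1405 higher and 1569 lower in the knockout. Socs3 differed by −4.71 ± 0.37, Il1b by −5.31 ± 0.48, Acod1 by −3.70 ± 0.30 and Saa3 by −3.37 ± 0.09 (edgeR adjusted p at most 1.23e-05). Lower responses were found for 28 of 28 interferon-stimulated genes (median −1.50, camera adjusted p = 3.19e-57, adjusted p = 0.0255 with estimated correlation) and for 17 of 22 NF-kB genes, or 18 adjusted over the list, such as Sod2 (−1.75 ± 0.08; median −0.73, adjusted p = 1.45e-17, adjusted p = 0.0272 with estimated correlation). Likewise lower were 15 of 23 cytokines and chemokines, or 16 adjusted over the list (median −1.80, adjusted p = 1.61e-08, adjusted p = 0.142 with estimated correlation), and 15 of 20 cholesterol synthesis genes, or 18 adjusted over the list, such as Mvd (−0.84 ± 0.11; median −0.45, adjusted p = 2.62e-11, adjusted p = 0.0255 with estimated correlation).

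**Figure D2:**
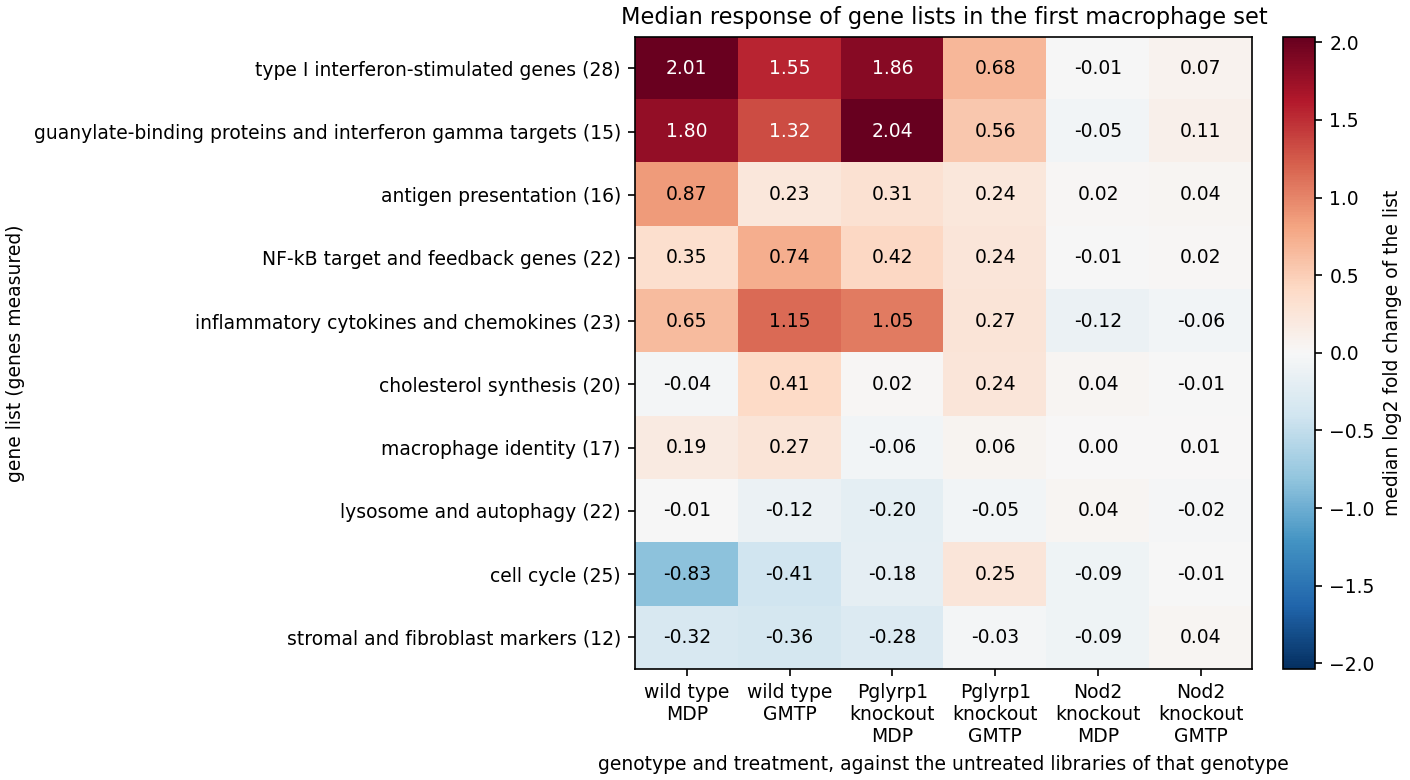
Median log2 fold change of 10 gene lists (rows, number of genes measured in brackets) for each genotype and treatment of the first macrophage set against its untreated libraries, n = 2 per group. The median of the type I interferon-stimulated genes was 2.01 and 1.55 in wild type, 1.86 and 0.68 in Pglyrp1-deficient and −0.01 and 0.07 in Nod2-deficient cells for MDP and GMTP.

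Cells labelled deficient in Pglyrp1, which encodes a secreted peptidoglycan-binding protein, were treated alike. With MDP the surface antigen gene Ly6i rose by 4.94 ± 0.18, Cxcl9 by 4.81 ± 0.10, Ccl5 by 4.00 ± 0.07 and Gbp2 by 2.92 ± 0.06. The scavenger receptor gene Marco rose by 2.68 ± 0.13, Mx1 by 2.62 ± 0.06 and Irf7 by 2.19 ± 0.05, while Gprc5c (−3.57 ± 0.09) and Myc (−2.42 ± 0.12) fell (n = 2 per group, edgeR adjusted p at most 4.97e-15). All 28 interferon-stimulated genes rose, with a median of 1.86 (camera adjusted p = 1.15e-44, adjusted p = 0.0367 with estimated correlation). In total 2910 genes rose and 3334 fell. Compared with the wild-type response, 635 genes responded more and 1249 less. The chemokine genes Cxcl9 (2.23 ± 0.14) and Ccl5 (1.77 ± 0.08) and the replication genes Rrm2 (1.42 ± 0.11) and Mcm5 (0.93 ± 0.10) had more positive responses. So did 19 of 25 cell cycle genes, or 22 adjusted over the list (adjusted p = 6.98e-26, adjusted p = 0.0384 with estimated correlation). Irf7 (−0.58 ± 0.07), Ciita (−0.78 ± 0.07) and Gprc5c (−1.68 ± 0.13) had more negative ones. So did 14 of 28 interferon-stimulated genes, or 18 and 1 the other way adjusted over the list (median −0.27, adjusted p = 9.95e-11, adjusted p = 0.36 with estimated correlation). The 7 genes just named differed in the opposite direction in untreated knockout cells, Ccl5 by −1.54 and Irf7 by 1.27, so part of each difference may reflect the starting level. The Nod2 response did not differ (−0.28 ± 0.13, adjusted p = 0.199). The count of 1884 differing genes was 1115 without wild-type MDP replicate 1, 1188 without untreated knockout replicate 1, 1193 without knockout MDP replicate 1 and 1216 without untreated wild-type replicate 2.

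GMTP changed far fewer genes in Pglyrp1-deficient cells, with 621 higher and 181 lower against 2250 and 1994 in wild type. Il1b (0.63, edgeR adjusted p = 0.316) and Socs3 (0.13, adjusted p = 0.927) were not called. Acod1 rose by 1.05 (adjusted p = 0.017), a call lost without GMTP replicate 1 (1.00), GMTP replicate 2 (1.09) or untreated replicate 2 (0.81). Interferon-stimulated genes still rose, Ifi44 by 1.21 ± 0.07, Mx1 by 0.98 ± 0.06 and Irf7 by 0.87 ± 0.05. The complement gene C3 rose by 1.5 ± 0.07 and the arginine synthesis gene Ass1 by 1.20 ± 0.06, while the haemoglobin scavenger gene Cd163 fell by 1.16 ± 0.16. The interferon list had 27 of 28 genes higher, or 28 adjusted over the list, with a median of 0.68 (camera adjusted p = 5.15e-85, adjusted p = 0.00445 with estimated correlation). Of 20 cholesterol synthesis genes 10 rose, or 16 adjusted over the list (median 0.24, adjusted p = 1.15e-14, adjusted p = 0.00445 with estimated correlation). The count of 802 fell to 424 without GMTP replicate 1, 482 without GMTP replicate 2 and 520 without untreated replicate 2.

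The difference between the Pglyrp1-deficient and the wild-type response to GMTP passed the threshold for 2090 genes, 1126 higher and 964 lower. Il1b differed by −4.96 ± 0.37, Socs3 by −4.58 ± 0.34, Acod1 by −2.71 ± 0.29 and Cxcl2 by −2.20 ± 0.32. Gbp7 differed by −2.16 ± 0.10, Bcl3 by −1.87 ± 0.13, Sod2 by −1.51 ± 0.08 and Nod2 by −0.52 ± 0.13 (n = 2 per group, edgeR adjusted p at most 0.00869). The Nod2 call was lost without knockout GMTP replicate 1 (−0.47), untreated knockout replicate 1 (−0.44) or untreated wild-type replicate 1 (−0.46). Smaller responses were seen in 14 of 22 NF-kB genes, or 17 adjusted over the list (median −0.63, camera adjusted p = 2.9e-17, adjusted p = 0.0373 with estimated correlation) and in 27 of 28 interferon-stimulated genes (median −0.74, adjusted p = 2.17e-44, adjusted p = 0.0373 with estimated correlation). The same was seen in 11 of 15 guanylate-binding proteins and interferon gamma targets, with 1 larger adjusted over the list (median −0.89, adjusted p = 3.58e-13, adjusted p = 0.0373 with estimated correlation) and in 10 of 23 cytokines and chemokines, or 12 adjusted over the list, with 1 larger (median −1.29, adjusted p = 8.85e-07, adjusted p = 0.19 with estimated correlation). Untreated knockout cells already held the interferon-stimulated genes higher than wild type, by a median of 0.83. After GMTP the list stood 0.03 from wild type, whereas the cytokine list stood at −1.44 and the NF-kB list at −0.60 from treated wild type. Cell cycle genes responded less negatively, with 21 of 25 higher, or 22 adjusted over the list (median 0.67, adjusted p = 4.35e-22, adjusted p = 0.0373 with estimated correlation).

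**Figure D3:**
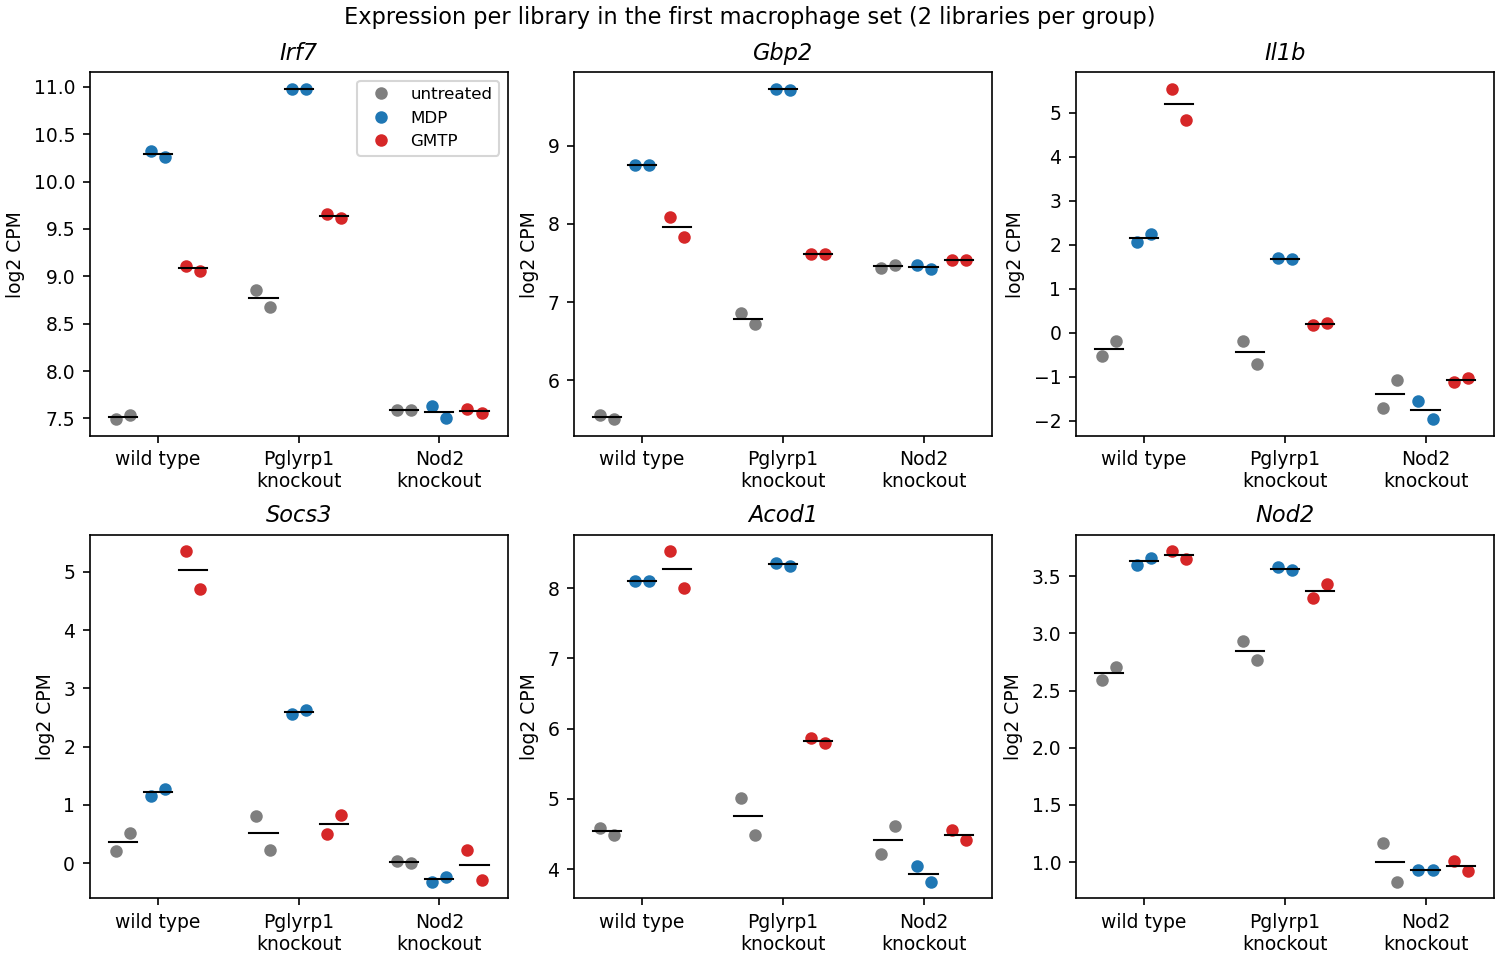
Log2 CPM of Irf7, Gbp2, Il1b, Socs3, Acod1 and Nod2 in each library of the first macrophage set (points, 2 per group) with the group mean (line). With GMTP the wild-type libraries stood far above untreated for Il1b (log2 fold change 5.59) and Socs3 (4.71), while the Pglyrp1-deficient libraries changed by 0.63 and 0.13.

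Untreated knockout cells of the first set differed widely from untreated wild type, and genotype could not be separated from the sex of the animals. Xist differed by −9.23 ± 0.19 in Pglyrp1-deficient and −9.67 ± 0.20 in Nod2-deficient cells, and the Y-linked gene Ddx3y by 8.19 ± 0.12 and 7.93 ± 0.12 (n = 2 per group, edgeR adjusted p at most 1.95e-11). Both knockouts held Vegfa, an angiogenic growth factor gene, higher by 4.06 ± 0.08 and 3.99 ± 0.08 and the clock output gene Dbp higher by 2.66 ± 0.10 and 2.94 ± 0.10. The fractalkine receptor gene Cx3cr1 was lower (−3.01 ± 0.10 and −5.33 ± 0.13), as was Ccl5 (−1.54 ± 0.06 and −1.89 ± 0.06), and Apoe was lower (−2.77 ± 0.08) in Pglyrp1-deficient cells. All 28 interferon-stimulated genes were higher in Pglyrp1-deficient cells (median 0.83, camera adjusted p = 5.93e-40, adjusted p = 0.0302 with estimated correlation), with Irf7 at 1.27 ± 0.05 and Mx1 at 1.37 ± 0.06. In Nod2-deficient cells 24 of 28 were higher (median 0.45, adjusted p = 7.49e-15, adjusted p = 0.132 with estimated correlation). Cholesterol synthesis genes were lower, 18 of 20 in Pglyrp1-deficient cells (median −1.10, adjusted p = 4.59e-33, adjusted p = 0.000363 with estimated correlation). In Nod2-deficient cells 18 were lower, or 19 adjusted over the list (median −0.64, adjusted p = 1.76e-17, adjusted p = 0.00591 with estimated correlation). Markers of another cell type moved as well. Of these, 10 of 12 stromal and fibroblast markers were lower in Pglyrp1-deficient cells, or 11 adjusted over the list, with Col1a1 at −2.48 ± 0.09 and Postn at −3.24 ± 0.11 (median −1.95, adjusted p = 8.81e-18, adjusted p = 0.000363 with estimated correlation). In Nod2-deficient cells 9 were lower (median −1.08, adjusted p = 7.08e-09, adjusted p = 0.00618 with estimated correlation). Nod2 differed by −1.65 ± 0.11 in Nod2-deficient cells (adjusted p = 5.7e-12) and was not called in Pglyrp1-deficient cells (0.21 ± 0.10, adjusted p = 0.124). The counts were 3634 genes in Pglyrp1-deficient cells, which fell to 2412 without untreated wild-type replicate 1, and 5172 in Nod2-deficient cells.

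The second set repeated the wild-type comparisons at 3 libraries per group. MDP changed 9 of 16228 genes under the labels as given. H2-Q5, a nonclassical MHC class I gene (0.94 ± 0.17), and Tnip1, which restrains NF-kB signalling (0.31 ± 0.06), rose. Frmd6 (−0.56 ± 0.09), Tspan13, Cpeb2, Arrdc3, Klf9, Ube2h and Fam117b fell (n = 3 per group, edgeR adjusted p at most 0.044). Irf7 (0.76 ± 0.23, adjusted p = 0.243), Cxcl9 (2.07 ± 0.46, adjusted p = 0.0789) and Tnfaip3, another NF-kB inhibitor gene (0.41 ± 0.10, adjusted p = 0.13), were not called. As groups, NF-kB genes had 1 of 22 higher, or 13 adjusted over the list (median 0.35, camera adjusted p = 3.36e-12, adjusted p = 0.0954 with estimated correlation). Interferon-stimulated genes had 0 of 28, or 25 adjusted over the list (median 0.58, adjusted p = 2.04e-17, adjusted p = 0.285 with estimated correlation). Cholesterol synthesis genes had 0 of 19, or 16 adjusted over the list (median 0.24, adjusted p = 2.11e-17, adjusted p = 0.0543 with estimated correlation). The count of genes depended on which libraries were fitted together, and 1676 genes had an unadjusted p under 0.05. There were 928 genes called (548 higher, 380 lower) in a fit without the 6 libraries whose targeted gene went against the label, a setting chosen after the data were seen. Leaving out any 1 of the 6 libraries compared gave 0, or 1 without untreated replicate 3.

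GMTP in wild-type cells of the second set raised 364 genes and lowered 87, with 48 and 2 changing at least 2-fold. Saa3 rose by 2.76 ± 0.47, the dicarboxylate transporter gene Slc13a3 by 2.52 ± 0.37, Clec4e by 2.37 ± 0.42, the glutathione transferase gene Gsta3 by 1.92 ± 0.23 and Hp, the haptoglobin gene, by 1.63 ± 0.26 (n = 3 per group, edgeR adjusted p at most 0.00208). Of 22 NF-kB genes 12 rose, or 14 adjusted over the list, such as Tnip1 (0.46 ± 0.06), Tnfaip3 (0.75 ± 0.10) and Sod2 (0.93 ± 0.14; median 0.47, camera adjusted p = 2.51e-18, adjusted p = 0.0112 with estimated correlation). The cytokine genes Cxcl2 (2.13 ± 0.48), Cxcl1 (2.93 ± 0.73) and Tnf (0.73 ± 0.19) were the 3 called of 22, or 5 adjusted over the list (median 0.23, adjusted p = 0.023, adjusted p = 0.363 with estimated correlation). Interferon-stimulated genes had 7 of 28 higher, or 25 adjusted over the list, with Irf7 at 0.86 ± 0.23 (median 0.66, adjusted p = 8.77e-18, adjusted p = 0.156 with estimated correlation). Cholesterol synthesis genes had 10 of 19 higher, or 17 adjusted over the list, with Mvd at 0.50 ± 0.08 (median 0.31, adjusted p = 1.07e-22, adjusted p = 0.0102 with estimated correlation). NRF2 targets, which defend against oxidants, had 6 of 14, or 8 adjusted over the list, with the cystine carrier gene Slc7a11 at 0.71 ± 0.13 (median 0.20, adjusted p = 2.05e-07, adjusted p = 0.0164 with estimated correlation). Glycolysis and hypoxia genes had 6 of 22, or 9 adjusted over the list (median 0.12, adjusted p = 2.9e-05, adjusted p = 0.0102 with estimated correlation). Tlr2 (0.66 ± 0.12), Msr1 (0.42 ± 0.06) and Marco (1.81 ± 0.36) rose, and Nod2 was not called (0.30 ± 0.28, adjusted p = 0.727). Leaving out 1 of the 6 libraries lowered the count from 451 to between 196 and 269. It was 196 without untreated replicate 1 or 2, 199 without untreated replicate 3, 212 without GMTP replicate 3, 253 without GMTP replicate 1 and 269 without GMTP replicate 2. Tnf and Irf7 were called in none of those 6 fits, Cxcl2 in none that left out an untreated library, and Cxcl1 not without GMTP replicate 1 or untreated replicate 1 or 3. Without the 6 libraries against the label the count was 1361.

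Directly compared, GMTP exceeded MDP in the second set for 71 genes and fell below it for 31. The genes higher with GMTP were led by Slc13a3 (1.86 ± 0.35) and Gsta3 (1.34 ± 0.22). They included 6 of 14 NRF2 targets, or 9 adjusted over the list, such as Slc7a11 (0.91 ± 0.13), Txnrd1 (0.31 ± 0.05) and Hmox1 (0.22 ± 0.04; n = 3 per group, edgeR adjusted p at most 0.00935). The NRF2 list had a median of 0.28 (camera adjusted p = 2e-13, adjusted p = 0.00199 with estimated correlation). Slc13a3 lost its call without GMTP replicate 3 (1.81) or any 1 MDP library (1.84 to 1.88). Without 1 library the count of 102 was 48, 45 and 30 without GMTP replicates 1, 2 and 3, and 26, 37 and 53 without MDP replicates 1, 2 and 3. It was higher with no low-count filter (612), without the 6 libraries against the label (778) and with wild type and Arhgef2 knockout alone (871). The MDP and GMTP responses here shared 2 genes higher and 5 lower, with 0.0449 and 0.0375 expected. Unchanged groups simulated against the same controls gave 0.05 and 0. A covariance of 0.116 (0.097 simulated) cannot show what comes from shared controls, as the 6 libraries may widen fitted dispersions. The 7 shared genes were 0 without untreated replicate 1 or 2 and 1 without untreated replicate 3, but 74 with DESeq2, 393 with no low-count filter, 492 without the 6 libraries and 589 with wild type and Arhgef2 knockout alone.

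Responses were compared between the sets, which share no library and whose wild-type cells differ in sex (Xist at 278 ± 42.7 CPM in the first set and 0.0214 ± 0.035 CPM in the second). The 2804 genes that rose with MDP in wild type of the first set and were measured in the second had a median log2 fold change of 0.05 with MDP there, with 70.6% moving the same way (fry p = 0.0477). The 2229 genes for GMTP had a median of 0.10 with 77.5% moving the same way (fry p = 0.000469). Among the 100 with the smallest p in the first set, 96 were higher with MDP in the second set (median 0.44) and 99 with GMTP (median 0.57). Genes that fell in the first set had medians of −0.03 for both compounds (fry p = 0.0724 for MDP and 0.0522 for GMTP). Across 15848 genes the fold changes of the sets correlated at r = 0.16 for MDP and 0.19 for GMTP. First-set MDP against second-set GMTP gave r = 0.26, with 270 genes higher in both (64.4 expected), and first-set GMTP against second-set MDP r = 0.13. Differences between these correlations were not tested. With GMTP 259 genes rose in both sets, where 51.2 were expected by chance, 42 fell in both, where 10.8 were expected, and 21 moved in opposite directions. The difference between GMTP and MDP did not agree between the sets overall (r = −0.07), with 26 genes higher in both (7.03 expected), 1 lower in both (3.58 expected) and 30 in opposite directions. With wild type and Arhgef2 knockout alone these were 127, 16 and 318.

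Arhgef2-deficient macrophages were included in the second set to ask whether GEF-H1 is needed. Under the labels, MDP raised 371 genes and lowered 165 in these cells, with 24 of 28 interferon-stimulated genes higher, or 27 adjusted over the list (median 0.93, camera adjusted p = 1.14e-34, adjusted p = 0.0622 with estimated correlation). The interferon-inducible gene Ifi208 rose by 2.71 ± 0.21, Ly6a by 2.08 ± 0.25, Irf7 by 1.13 ± 0.23 and the hexokinase gene Hk2 by 0.37 ± 0.04 (n = 3 per group, edgeR adjusted p at most 0.00766). In the same comparison Arhgef2 itself rose by 2.74 ± 0.59 (adjusted p = 0.0112), since 2 of the MDP libraries hold it near the wild-type level. The platelet integrin gene Itga2b (2.51 ± 0.51), Col1a1 (1.68 ± 0.35) and 7 of 14 stromal and fibroblast markers, or 11 adjusted over the list, rose too (median 1.53, adjusted p = 4.38e-09, adjusted p = 0.139 with estimated correlation). Without the 6 libraries against the label, which leaves 1 library with MDP in this genotype, Arhgef2 changed by 0.19, Itga2b by 0.71 and Col1a1 by 0.13, none of them called, and the stromal list was not called (adjusted p = 0.129). The count of 536 was 908 without MDP replicate 1, 306 without MDP replicate 2, 276 without MDP replicate 3, and 240, 276 and 164 without untreated replicates 1, 2 and 3. It was 1074 without the 6 libraries, with a single MDP library. The response to MDP differed from wild type for 6 genes, all higher: Tln2 (1.99 ± 0.34), Ifi208 (1.98 ± 0.29), Pde7b (0.64 ± 0.12), Hk2 (0.32 ± 0.06) and, chosen after their values were seen, Pdzrn3 (3.37) and 1600014C10Rik (0.53). That count became 544 without MDP replicate 1, and 2 or 3 without any of 7 other libraries: MDP replicate 3, untreated replicate 3, wild-type MDP replicates 1, 2 and 3 and untreated wild-type replicates 1 and 2.

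GMTP in Arhgef2-deficient cells gave 0 calls with edgeR, with 1389 genes at an unadjusted p under 0.05, 34 called by DESeq2 and 0 by limma-voom. It gave 5 without untreated replicate 1 and 1 without GMTP replicate 1, but 445 with no low-count filter, 385 without the 6 libraries against the label and 510 with wild type and Arhgef2 knockout alone. The 0 calls therefore do not show a lack of response. The inflammasome gene Nlrp3 (0.29 ± 0.07), Tlr2 (0.48 ± 0.12), the NF-kB feedback gene Birc3 (0.36 ± 0.10) and Mx1 (0.88 ± 0.26) had positive fold changes that were not called (n = 3 per group, edgeR adjusted p at least 0.191). As groups, 0 of 28 interferon-stimulated genes were called, or 25 higher adjusted over the list (median 0.56, camera adjusted p = 6.05e-22, adjusted p = 0.154 with estimated correlation). Among 22 NF-kB genes 0 were called, or 4 higher adjusted over the list (median 0.26, adjusted p = 1.86e-08, adjusted p = 0.154 with estimated correlation). The difference from the wild-type response passed the threshold with edgeR for 0 genes, with 937 at an unadjusted p under 0.05, 19 by DESeq2 and 0 by limma-voom. It did so for 168 with no low-count filter, 60 without the 6 libraries and 127 with wild type and Arhgef2 knockout alone. The nearest NF-kB genes were Tnfaip2 (−0.32 ± 0.07, adjusted p = 0.243) and Tnfaip3 (−0.55 ± 0.14, adjusted p = 0.363). Of 22 NF-kB genes 0 responded less, or 4 adjusted over the list (adjusted p = 1.73e-05, adjusted p = 0.332 with estimated correlation). Genes raised by GMTP in wild type of the first set had a median of 0.05 in Arhgef2-deficient cells with GMTP (fry p = 0.0521), and their difference from wild type of the second set gave fry p = 0.192.

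Untreated Arhgef2-deficient cells, whose 3 libraries all matched the label, differed from wild type by 1005 genes higher and 988 lower. Arhgef2 differed by −3.32 ± 0.60 (edgeR adjusted p = 0.000743, n = 3 per group). The scavenger receptor gene Marco was higher by 2.89 ± 0.34, Saa3 by 2.74 ± 0.47, Ccl5 by 2.59 ± 0.35 and the MHC class II genes Cd74 and H2-Ab1 by 1.00 ± 0.16 and 1.10 ± 0.18. Antigen presentation genes were higher in 10 of 16 cases (median 0.37, camera adjusted p = 1.6e-08, adjusted p = 0.202 with estimated correlation). Of 17 LXR targets, which export lipid, 9 were higher and 1 lower, or 11 higher adjusted over the list (median 0.29, adjusted p = 2.81e-07, adjusted p = 0.0175 with estimated correlation). Cholesterol synthesis genes were lower in 14 of 19 cases, or 15 adjusted over the list, with Stard4 at −0.75 ± 0.07 and Insig1 at −0.50 ± 0.05 (median −0.41, adjusted p = 2.42e-16, adjusted p = 0.033 with estimated correlation). Of 25 cell cycle genes 16 were lower and 1 higher, or 19 lower adjusted over the list, with Kif11 at −1.51 ± 0.30 (adjusted p = 7.79e-12, adjusted p = 0.342 with estimated correlation). Stromal and fibroblast markers were lower in 7 of 14 cases, or 8 adjusted over the list, with Col1a1 at −1.53 ± 0.35 (median −1.04, adjusted p = 4e-05, adjusted p = 0.345 with estimated correlation). The count of 1993 was 768 without untreated knockout replicate 2 and 1278, 1262 and 1138 without untreated wild-type replicates 1, 2 and 3. It rose to 3267 without the 6 libraries and 3337 with wild type and Arhgef2 knockout alone.

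The comparisons labelled Pglyrp1 and Nod2 knockout in the second set each used 2 untreated libraries against their label. Under the labels, the response to GMTP differed from wild type for 1661 genes in the Pglyrp1 knockout, with Saa3 at −4.03 ± 0.61, C3 at −3.82 ± 0.72 and 26 of 28 interferon-stimulated genes lower, or 27 adjusted over the list (n = 3 per group, edgeR adjusted p at most 0.00222; list median −1.19, camera adjusted p = 4.39e-20, adjusted p = 0.16 with estimated correlation). For the Nod2 knockout it differed for 914 genes, with Tnip1 at −0.65 ± 0.09 and 13 of 22 NF-kB genes lower, or 15 adjusted over the list (median −0.71, adjusted p = 7.97e-14, adjusted p = 0.104 with estimated correlation). Differences in the response to MDP numbered 14 for the Pglyrp1 knockout and 1517 for the Nod2 knockout, the latter with 22 of 25 cell cycle genes lower, or 25 adjusted over the list (median −1.55, adjusted p = 1.14e-16, adjusted p = 0.256 with estimated correlation). Against their own untreated libraries, the labelled Pglyrp1 knockout gave 115 genes with MDP and 709 with GMTP, and the labelled Nod2 knockout 1012 and 1086. Untreated, they differed from wild type by 3686 and 3228 genes. Without the 6 libraries, which leaves 1 untreated library per knockout, the 8 response counts fell. The differences from wild type fell to 0 and 75 for the Pglyrp1 knockout and 121 and 324 for the Nod2 knockout with MDP and GMTP, and the responses to 80 and 0 for the Pglyrp1 knockout and 0 and 0 for the Nod2 knockout. Leaving out the 1 untreated library that matched its label raised the counts, to 1903 and 3296 for the Pglyrp1 knockout and 3141 and 3215 for the Nod2 knockout.

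Colon biopsies with active ulcerative colitis were compared with healthy ones to show how peptidoglycan-sensing genes change in the inflamed mucosa. Large rises included antimicrobial epithelial genes. The regenerating lectin genes REG1B, REG3A and REG1A rose by 9.37 ± 1.31, 9.25 ± 1.14 and 9.10 ± 1.15. The acute-phase gene SAA1 rose by 8.45 ± 0.89, DUOXA2, which matures an oxidant-producing enzyme, by 8.20 ± 0.75 and the iron-binding lipocalin gene LCN2 by 5.54 ± 0.45 (12 active and 10 healthy biopsies, edgeR adjusted p at most 3.4e-06). REG1B and REG3A were not called by limma-voom (6.86 and 7.23). Of 22 antimicrobial epithelial genes 21 rose, or 22 adjusted over the list, with a median of 6.04 (camera adjusted p = 2.81e-09, adjusted p = 0.166 with estimated correlation). Neutrophil markers rose in 17 of 18 cases, with 1 lower adjusted over the list and FCGR3B at 7.74 ± 1.10, S100A8 at 6.64 ± 0.95 and AQP9 at 8.24 ± 1.16 (median 5.44, adjusted p = 3.03e-05, adjusted p = 0.312 with estimated correlation). Cytokines and chemokines rose in 27 of 28 cases, including the neutrophil attractant CXCL1 (5.97 ± 0.68), IL17A (5.88 ± 0.82) and IL1B (5.34 ± 0.87; median 4.05, adjusted p = 3.69e-08, adjusted p = 0.214 with estimated correlation). Without the 2 active biopsies farthest out on the first principal component, a fit added after the data were seen, IL1B rose by 3.71, FCGR3B by 5.73, S100A8 by 4.69 and AQP9 by 6.56. NF-kB genes rose in 16 of 22 cases, or 18 adjusted over the list, with TNIP3 at 6.54 ± 0.73 and the adhesion gene ICAM1 at 2.56 ± 0.31 (median 1.21, adjusted p = 2.52e-07, adjusted p = 0.166 with estimated correlation).

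Guanylate-binding proteins and interferon gamma targets rose in active disease in 17 of 19 cases, with GBP5 at 2.89 ± 0.29 (median 1.81, camera adjusted p = 8.23e-12, adjusted p = 0.166 with estimated correlation). Type I interferon-stimulated genes rose in 16 of 25 cases, or 19 adjusted over the list, with the nucleic acid sensor gene ZBP1 at 2.47 ± 0.24 (median 1.00, adjusted p = 2.39e-08, adjusted p = 0.166 with estimated correlation). Of 20 peptidoglycan sensing genes 11 rose, or 12 adjusted over the list, with RIPK2, the kinase downstream of NOD2, at 1.25 ± 0.19 and PGLYRP4 at 3.92 ± 0.86 (median 0.59, adjusted p = 0.00641, adjusted p = 0.221 with estimated correlation). Matrix remodelling genes rose in 23 of 24 cases, including MMP3 at 7.53 ± 1.15, or 5.01 without those 2 biopsies (median 2.94, adjusted p = 1.18e-11, adjusted p = 0.166 with estimated correlation). T cell markers rose in 14 of 15 cases, or 15 adjusted over the list, with the regulatory T cell gene FOXP3 at 2.47 ± 0.29 (median 1.40, adjusted p = 3.69e-08, adjusted p = 0.166 with estimated correlation).

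Genes of epithelial metabolism and transport fell in active disease. The tight junction gene CLDN8 fell by 7.10 ± 0.54 (edgeR adjusted p = 1.14e-09), as did the gluconeogenic gene PCK1 (−4.05 ± 0.53), the sulfate transporter gene SLC26A2 (−3.21 ± 0.47), the water channel gene AQP8 (−3.32 ± 0.86) and the ketone-handling gene ACAT1 (−1.31 ± 0.15). Mitochondrial fuel and epithelial metabolism genes fell in 19 of 20 cases (camera adjusted p = 9.08e-12, adjusted p = 0.166 with estimated correlation). Transporters and detoxification genes fell in 15 of 19, or 16 adjusted over the list (median −1.46, adjusted p = 9.73e-09, adjusted p = 0.166 with estimated correlation). Colonocyte markers fell in 15 of 23 (median −1.21, adjusted p = 4.2e-08, adjusted p = 0.221 with estimated correlation) and enteroendocrine markers in 9 of 12, with 1 higher and the somatostatin gene SST at −2.06 ± 0.40 (median −1.88, adjusted p = 0.000221, adjusted p = 0.246 with estimated correlation). Goblet cell markers had 8 of 16 lower and 2 higher (adjusted p = 0.0233, adjusted p = 0.432 with estimated correlation). Crypt stem and proliferation genes had 6 of 21 higher, or 5 adjusted over the list, and 1 lower (adjusted p = 0.0273, adjusted p = 0.505 with estimated correlation). Mitochondrially encoded transcripts took 13.5 ± 4.6% of counts in active and 20 ± 3.37% in healthy biopsies (two-sided permutation test with 100000 resamples, p = 0.0015). In total 5242 of 22620 genes rose and 4038 fell, 2760 and 1195 at least 2-fold. With markers of immune, stromal and epithelial cells all moving, a change in expression within cells was not separated from a change in the mix of cells.

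Active disease was also compared with inactive disease. REG1B was higher by 9.44 ± 1.67, the matrix protease gene MMP7 by 9.25 ± 1.08, LCN2 by 5.27 ± 0.56, CXCL1 by 4.79 ± 0.80 and GBP5 by 2.40 ± 0.35, while CLDN8 (−5.82 ± 0.54) and PCK1 (−3.57 ± 0.55) were lower (12 active and 6 inactive biopsies, edgeR adjusted p at most 0.000179). Antimicrobial epithelial genes were higher in 20 of 22 cases, or 22 adjusted over the list (median 5.10, camera adjusted p = 1.51e-10, adjusted p = 0.181 with estimated correlation). Neutrophil markers were higher in 16 of 18, or 17 with 1 lower adjusted over the list (median 5.89, adjusted p = 3.82e-05, adjusted p = 0.305 with estimated correlation), and peptidoglycan sensing genes in 8 of 20 (median 0.42, adjusted p = 0.0117, adjusted p = 0.292 with estimated correlation). Transporters and detoxification genes were lower in 14 of 19 cases (median −1.54, adjusted p = 1.98e-08, adjusted p = 0.181 with estimated correlation). The counts were 3960 genes higher and 3031 lower. Inactive disease differed from healthy colon for 2 genes with edgeR, both higher: ADAT2, a tRNA-editing enzyme gene (0.67 ± 0.12, adjusted p = 0.0376), and, chosen after its values were seen, the noncoding gene AL121821.2 (5.11, adjusted p = 0.0376), which was 6.02 higher in active than in healthy colon. There were 1821 genes at an unadjusted p under 0.05, and DESeq2 called 60, of which 43.3% were higher, and limma-voom 1. By list, type I interferon-stimulated genes were higher, with 0 of 25 called, or 1 adjusted over the list (median 0.43, camera adjusted p = 0.00174, adjusted p = 0.968 with estimated correlation). Mitochondrial fuel and epithelial metabolism genes (median −0.23, adjusted p = 0.00174) and enteroendocrine markers (median −0.38, adjusted p = 0.0121) were lower with 0 genes called (adjusted p = 0.968 for both with estimated correlation).

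In colon the human counterparts of the targeted genes behaved differently from each other. NOD2 (ENSG00000167207.14) stood at 6.89 ± 4.38 CPM in active and 2.19 ± 0.76 CPM in healthy biopsies. It was higher in active disease by 1.66 ± 0.28 against healthy (12 and 10 biopsies, edgeR adjusted p = 2.89e-05) and by 1.33 ± 0.33 against inactive colon (12 and 6 biopsies, edgeR adjusted p = 0.00323). PGLYRP1 (ENSG00000008438.5), which neutrophils store in their granules, was low, at 0.503 ± 0.761 CPM in active and 0.184 ± 0.15 CPM in healthy biopsies. It was not called (1.43 ± 0.60, edgeR adjusted p = 0.0563), though DESeq2 called it (1.44). Without the same 2 active biopsies it changed by 0.52. ARHGEF2 (ENSG00000116584.20) was not called either (−0.13 ± 0.10, adjusted p = 0.324). In inactive against healthy colon neither NOD2 (0.32 ± 0.32) nor PGLYRP1 (0.05 ± 0.73) was called. Within each group the 3 genes were correlated with the mean of 18 measured neutrophil markers, which makes 9 relations. In the 12 active biopsies PGLYRP1 gave r = 0.75 (permutation p = 0.0174, adjusted p = 0.0782) and rho = 0.65 (permutation p = 0.0259). NOD2 gave r = 0.72 (p = 0.0138, adjusted p = 0.0782) and rho = 0.62 (p = 0.0375), and ARHGEF2 r = 0.74 (p = 0.0263, adjusted p = 0.0788) and rho = 0.41 (p = 0.185), by two-sided permutation tests. Without the 2 biopsies farthest from the median score r was 0.58 (p = 0.084), 0.30 and 0.23, so the relations of NOD2 and ARHGEF2 rest largely on those biopsies. In the 10 healthy biopsies r was 0.26, 0.35 and 0.24 and in the 6 inactive ones 0.12, 0.67 and −0.10 for PGLYRP1, NOD2 and ARHGEF2. None of the 9 relations passed the threshold after adjustment.

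**Figure D4:**
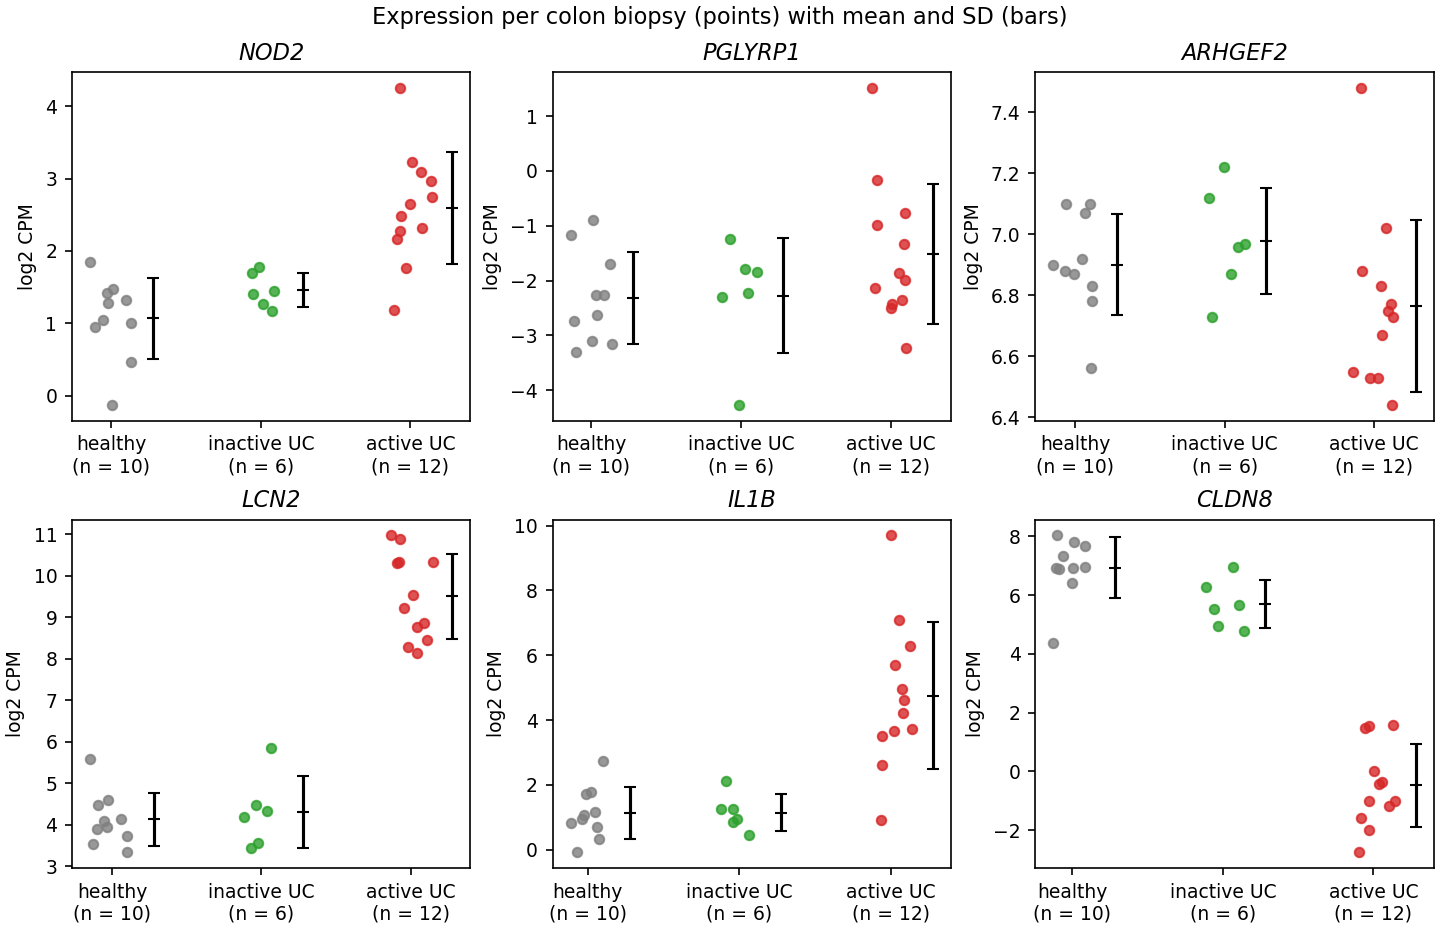
Log2 CPM of NOD2, PGLYRP1, ARHGEF2, LCN2, IL1B and CLDN8 in each colon biopsy (points; 10 healthy, 6 inactive and 12 active ulcerative colitis), with mean and SD beside each group. NOD2 was higher in active than in healthy biopsies by a log2 fold change of 1.66 and CLDN8 lower (−7.10), while PGLYRP1 (1.43) did not pass the threshold.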

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

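The tests of mislabelling, mixing and displaced labels, of the neighbours of targeted genes and of the 2 lists in treated cells were chosen after the results were seen; those of the knockout baseline, of sex and of other splits were planned.

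In 6 of 36 libraries of the second macrophage set a targeted gene went against the label. All 6 correlated best, over genes away from the targeted loci, with libraries of another genotype than the labelled one, while 30 of the other 30 correlated best with their own, which is consistent with wrong labels. A mixture is argued against by the levels of the targeted genes: the share of RNA from another genotype they imply was at least 90.3% in all 6. A shift of the knockout labels by 2 places in an assumed order, which no source gives, is a candidate. It gave the lowest variance within groups of 20 shifts and of 228 arrangements (0.898 of that under the labels). It was chosen with the 6 known, so this decides nothing. Such a shift would also move treatment labels among Pglyrp1 and Nod2 knockout libraries counted as matching, so the counts without the 6 libraries depend on those labels too. No library was regrouped.

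Responses to MDP and GMTP differed between labelled genotypes by the test of the difference itself, though genotype ran with sex in the first set. In the first set this held for 1884 and 2090 genes in Pglyrp1-deficient cells and for 3263 and 2974 genes in Nod2-deficient cells. In the second set it held for 14 and 1661 genes in the labelled Pglyrp1 knockout, 1517 and 914 in the labelled Nod2 knockout and 6 for MDP in the labelled Arhgef2 knockout.

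The smaller GMTP response of Pglyrp1-deficient cells in the first set covered 907 of the 2250 genes that rose in wild type, with a median response of 0.55 in wild type and 0.08 in the knockout. These genes were already higher in untreated knockout cells, by a median of 0.18. In treated cells they were lower than in treated wild type by a median of −0.23 (755 of 907 lower), which leaves open how far the baseline accounts for the difference. For the interferon-stimulated genes treated cells differed by 0.03, so a higher baseline may account for their smaller response; for cytokines and chemokines treated cells were lower by −1.44, which a higher baseline cannot give. Sex cannot be told from genotype in this set. In male wild-type cells of the second set 729 of 904 of these genes were higher with GMTP (median 0.13). The 2229 of 2250 measured there had a median of 0.10, so this cannot decide. Loss of PGLYRP1 and sex stay open.

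Genes near Pglyrp1 were called more often than others in untreated Pglyrp1-deficient cells of the first set: 80 of 244 within 10 Mb (32.8%) against 20.9% elsewhere (odds ratio 1.84, Fisher's exact p = 1.75e-05). This is consistent with DNA of another strain carried along with the targeted locus, which may account for some calls near it. Near Nod2 the odds ratio was 1.19 (p = 0.286) and near Arhgef2 in the second set 1.41 (p = 0.0484), and neither decides. No strain variant was examined.

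Other splits of the same libraries were counted for groups of at least 3. In the second set there are 10 splits, too few for a share under 0.05; the real count and the highest other were 9 and 0 for MDP and 451 and 0 for GMTP in wild type (1 split as large in each), and 102 and 0 for GMTP against MDP (1). For the labelled Pglyrp1 knockout they were 115 and 993 (3) and 709 and 1439 (2), for the labelled Nod2 knockout 1012 and 1045 (2) and 1086 and 1679 (2), and for the Arhgef2 knockout 536 and 458 (1) and 0 and 0 (10). Differences from wild type gave 14 and 2570 (10) and 1661 and 1528 (1) for Pglyrp1. For Nod2 they were 1517 and 1931 (2) and 914 and 1660 (4). For Arhgef2 they were 6 and 916 (4) and 0 and 490 (10). Which splits gave counts far above the real one was not examined, and the 490 compare none of the 6 libraries. Untreated knockouts gave 3686 and 599, 3228 and 163, and 1993 and 0 for Pglyrp1, Nod2 and Arhgef2 (1 each). In colon 1 of 100 splits, the real one, was as large in each comparison. For active against healthy (9280 and 157) and against inactive (6991 and 4712) chance is argued against. For inactive against healthy (2 and 1) this cannot decide, as no low-count filter and limma-voom each call 1 there. Which biopsies the split with 4712 genes exchanged was not examined.

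In colon 1 biopsy stood apart from its group for some named genes. Among healthy biopsies the gap divided by the range was 0.507 for TNIP3, 0.613 for RIPK2, 0.557 for CLDN8, 0.672 for SLC26A2, 0.614 for AQP8, 0.511 for SST and 0.607 for MT1M, each above Dixon's 95% critical value for that group size. In inactive ones it was 0.63 for ICAM1, also above, and 0.651 for PGLYRP1. There the log-scale floor sets the lowest value, so the ratio decides nothing. These are 9 of 82 tests (about 4.1 by chance). Active biopsies were not tested.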

How the results depend on the processing

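The fits without the 6 libraries against the label, with wild-type and Arhgef2-deficient libraries alone, without the 2 active biopsies farthest out on the first principal component and without mitochondrially encoded genes were tests chosen after the data were seen; the others were planned. In the first set and in colon, counts stayed within 1.5 times of the reported count under RLE size factors, limma-voom, DESeq2, no low-count filter and, in colon, both added fits, except as given here; RLE size factors moved no count of any set beyond that, though of the 9 genes called with MDP in wild type of the second set 6 were called. For the genes named in the text, 1271 values kept direction and side of the threshold in the first set, with 19 weaker, 5 stronger and 7 moved, 329 in colon, with 8 weaker, 3 stronger and 2 moved, and in the second set 744 did, with 152 weaker and 33 stronger. Lists kept their call in 466, 292 and 83 values of the first set, the second set and colon, and lost it in 31, 26 and 27, mostly with estimated correlation, under which 59 of 378 calls remain. The cause of each change below was not tested. Pairs of counts run in the order MDP then GMTP.

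Without a low-count filter the Nod2 knockout of the first set gave 24 and 152. In the second set it gave 651 and 930 for wild type, 1004 and 1772 for Pglyrp1, 1782 and 1771 for Nod2 and 1149 and 445 for Arhgef2 knockout, and 612 for GMTP against MDP. Differences from wild type were 1035 for Pglyrp1 knockout with MDP, 1760 for Nod2 knockout with GMTP and 652 and 168 for Arhgef2 knockout. The shared response was 393 and inactive colon 1. With DESeq2 the Nod2 knockout of the first set gave 11 and 104. In the second set wild type gave 120 and 756, Pglyrp1 knockout 338 and 1300, Arhgef2 knockout 823 and 34, and GMTP against MDP 242. Differences from wild type were 228 for Pglyrp1 knockout with MDP, 1460 for Nod2 knockout with GMTP and 43 and 19 for Arhgef2 knockout, the shared response was 74 and inactive colon 60. With limma-voom wild type with MDP gave 25, the Arhgef2 difference with MDP 1 and inactive colon 1, or 70 with sample quality weights. A replicate block moved no count of the first set beyond 1.5 times. The second set gave with it 1 and 249 for wild type, 19 and 212 for Pglyrp1 knockout, 653 for Nod2 knockout with GMTP, 190 for Arhgef2 knockout with MDP, 45 for GMTP against MDP, differences of 0 for Pglyrp1 knockout with MDP, 498 for Nod2 knockout with GMTP and 3 for Arhgef2 knockout with MDP, and a shared response of 1.

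Without the 6 libraries, which leaves 1 library in each of 3 groups, wild type gave 928 and 1361, Pglyrp1 knockout 0 with GMTP, Nod2 knockout 0 and 0, Arhgef2 knockout 1074 and 385, and GMTP against MDP 778. Differences from wild type were 0 and 75 for Pglyrp1, 121 and 324 for Nod2 and 34 and 60 for Arhgef2 knockout; untreated, Pglyrp1 knockout differed by 906 and Arhgef2 knockout by 3267, and the shared response was 492. The median response in the second set of genes raised by MDP in the first reversed in labelled Pglyrp1 knockout to 0.062, that of genes lowered to −0.013, and that of genes raised by GMTP to 0.019. Other medians that crossed the threshold were −0.025 and −0.029 for genes lowered in wild type by MDP and GMTP, 0.014 and 0.001 for genes lowered by GMTP in Pglyrp1 and Nod2 knockout, and 0.043 for genes raised by GMTP in Arhgef2 knockout. Stromal markers with MDP in Arhgef2 knockout reversed direction in camera (adjusted p = 0.129). With wild-type and Arhgef2-deficient libraries alone the values were 1045 and 1408, 1137 and 510, 871 for GMTP against MDP, differences of 147 and 127, 3337 untreated, a shared response of 589, 0.045 for genes raised by GMTP in Arhgef2 knockout, −0.026 for genes lowered by GMTP in wild type and a reversed stromal list (adjusted p = 0.136). With the 100 genes of smallest p, medians were −0.106 for genes lowered by MDP in wild type, 0.04 and 0.015 for genes lowered by MDP and GMTP in Pglyrp1 knockout and 0.437 for genes raised by GMTP in Arhgef2 knockout. Without 2 biopsies the correlation with the neutrophil score in inactive colon went from 0.67 to −0.29 for NOD2, from −0.10 to 0.60 for ARHGEF2 and from 0.12 to 0.95 for PGLYRP1, over 4 biopsies, and in healthy colon from 0.35 to 0.01 for NOD2 and from 0.24 to 0.06 for ARHGEF2, over 8.

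Leaving out 1 library at a time gave these lowest and highest counts. In the first set they were 424 and 558 for Pglyrp1 knockout with GMTP, 1 and 791 (without MDP replicate 1) for Nod2 knockout with MDP, 6 and 11 with GMTP, 1115 and 1833 for the Pglyrp1 difference with MDP and 2412 and 2831 for untreated Pglyrp1 knockout. In the second set they were 0 and 1 and 196 and 269 for wild type, 0 and 1903 and 2 and 3296 for Pglyrp1 knockout, 0 and 3141 and 0 and 3215 for Nod2 knockout, each highest without untreated replicate 3, and 164 and 908 (without MDP replicate 1) and 0 and 5 for Arhgef2 knockout. GMTP against MDP gave 26 and 53. Differences from wild type gave 0 and 1854 and 705 and 3476 for Pglyrp1 and 371 and 3273 and 221 and 2716 for Nod2 knockout, each highest without untreated knockout replicate 3, and 2 and 544 (without MDP replicate 1) for Arhgef2 knockout with MDP. Untreated knockouts gave 2002 and 4898 for Pglyrp1, 768 and 1827 for Arhgef2, and the shared response 0 and 1. Depth limits Pglyrp1, at 0 to 15 counts per library in the first set.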

Other observations

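None of the values in this part was tested further, and the genes were picked after their values were seen from those the naming rule gives.

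The metallothionein genes MT1X (−3.06 ± 0.40), MT1M (−3.35 ± 0.60) and MT1H (−3.28 ± 0.55) were lower in active than in inactive colon (12 and 6 biopsies, edgeR adjusted p at most 0.000213), and MT1M by −3.28 ± 0.56 than in healthy colon. No list of this gene family was tested. In active against healthy colon the Paneth cell defensin gene DEFA5 was higher by 8.44 ± 1.45, though not called by limma-voom (6.68), while the enterocyte genes RBP2 (−3.16 ± 0.42) and ALPI (−2.41 ± 0.30) were lower. Of the 7 ileal and proximal markers 4 were lower and 2 higher, and the list was not called (camera adjusted p = 0.0609). The squamous epithelial genes DSG3 (3.58 ± 0.81) and TP63 (2.26 ± 0.39) were higher (edgeR adjusted p at most 0.000827 for these 5 genes), as were 3 of the 4 measured in their list, but the list was not called (camera adjusted p = 0.0614).

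In macrophages cholesterol synthesis genes were lower in untreated knockout cells, with medians of −1.10 and −0.64 in Pglyrp1- and Nod2-deficient cells of the first set and −0.41 in Arhgef2-deficient cells of the second, and GMTP raised them in wild type of both sets, by 0.41 and 0.31. The immediate early gene Fos differed by −1.26 ± 0.05 in untreated Pglyrp1-deficient and −2.12 ± 0.06 in untreated Nod2-deficient cells, and the collagenase gene Mmp8 was higher by 2.32 ± 0.05 in Nod2-deficient cells (n = 2 per group, edgeR adjusted p at most 1.61e-15). Of 7 megakaryocyte markers 6 were higher and 1 lower in untreated Nod2-deficient cells (median 2.01, camera adjusted p = 0.000792, adjusted p = 0.0836 with estimated correlation).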
